A study of Homo sapiens with 10 samples.

How the data were processed

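The series holds RNA-seq of U251 glioma cells with a regulatory element of HOTAIR knocked out, in 8 libraries, and 2 Capture Hi-C samples of unedited cells. Per the labels, total RNA was depleted of ribosomal RNA and sequenced on an Illumina HiSeq instrument, and cells were treated with TMZ at 1 mM or DMSO for 72 h. No processed file came with the Capture Hi-C samples, so they are not analysed here. The labels gave the knockout line, the treatment and a replicate number, and from these the libraries were put in 4 groups of 2. The labels do not say whether the replicates were separate cultures, so they may be technical, and the errors given may then miss the variation between cultures.

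The values are deposited read counts per gene, which per the labels the authors made with HISAT2 2.1.0 on hg19 and HTSeq 0.9.1, with DESeq2 1.18.1 for their own tests and Bowtie2 2.3.1 in their workflow. The annotation release and the strand setting are not stated, so antisense and overlapping genes, and paralogs such as AKR1C, IFITM, OAS and histone genes, may share reads. Each file had 56648 gene rows and 5 counter rows for reads not assigned to a gene, and 29615 genes had at least 1 count. Totals in genes were 10332900 to 17396200 per library, where 3 counts correspond to 0.184 to 0.309 CPM. Of the reads in each file, 10.3% to 12.1% were ambiguous, 16.3% to 17.9% not unique, 1.42% to 2.61% not aligned, and 3.65% to 5.01% outside genes. The share outside genes was 3.65% and 3.67% in KO1_DMSO and 4.60% to 5.01% in the other libraries. The replicates in a group differed by a chi-square per degree of freedom of 2.80 in KO1_DMSO, 4.44 in KO1_TMZ, 2.09 in KO2_DMSO and 2.16 in KO2_TMZ.

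Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the package's default expression filter (15152 genes), scaled by trimmed mean of M values (factors 0.933 to 0.942 in DMSO and 1.06 to 1.07 in TMZ), and fitted with 1 mean per group by robust quasi-likelihood, with 4 residual degrees of freedom, a median prior of 67.25 and a common biological coefficient of variation of 4.55%. Contrasts from this fit gave the TMZ response in KO1, in KO2 and in their mean, the difference between the responses (KO2 minus KO1), and the difference between KO2 and KO1 in DMSO and in TMZ. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 from edgeR. Standard errors are approximate: each is the size of the fitted log2 fold change divided by the square root of its F statistic. They can be too small where a group had only a few counts. Intervals for ratios with few counts are exact 95% intervals that cover counting error only, as do floors of 3 counts.

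Before the data were examined, 26 gene lists were written from textbook knowledge. The 23 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with an adjusted p over the lists. The same lists were tested with an estimated correlation, and with fry, which asks whether a list moved at all and not whether it moved more than other genes. Genes named without a list are the 10 with the largest called changes in each direction at a mean of at least 5 CPM whose single libraries all differed in that direction, for the mean response, the difference between responses and the difference in DMSO. Genes named from a tested list are among its 4 members with the lowest p in that comparison, so their values are larger than those of a typical member. NQO1 and EGR1, and the lists they stand for, were chosen after the values were seen and were not tested as lists. Some genes are not reported here.

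Gene order came from a RefSeq table on GRCh38.p14, another build than that of the counts, so no positions are given; 13631 tested genes (90.0%) matched by name. Medians of the line difference over 31 neighbouring genes with at least 3 CPM were taken, and a run was kept where at least 50 windows on a chromosome passed 0.25 in one direction. Each run spans from the first to the last of these windows, and windows between them need not pass.

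The procedure was tested on simulated data with 100 genes changed by a set factor. Of genes changed by a factor of 2, it recovered 85% for the mean response, 78% in KO1, 78% in KO2, 63% for the difference between responses, 75% for the lines in DMSO and 80% for the lines in TMZ, and of genes changed by 1.5 it recovered 66%, 60%, 64%, 60%, 54% and 62%. It called 5 to 17 unchanged genes. All 3 shifted lists were recovered in each list test, and fry also called 1 list that was not shifted, for the lines in DMSO. Simulated genes varied independently and few were changed. These shares may therefore not hold for lists of correlated genes, or with as many changes as were called in the data.

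Alternatives fixed from the labels alone were other scalings (relative log expression and upper quartile), no or a stricter filter (50 counts), the Wald test of DESeq2 1.42.0, a replicate block, a minimum change by a factor of 2, fits of only the groups compared, leaving out mitochondrial and abundant non-coding RNA genes before scaling, the other list tests, and leaving out each library. Added after the data were seen were thinning every library to the lowest gene count total, leaving out both KO2_DMSO or both KO1_TMZ libraries, and leaving out the runs of neighbouring genes. A scaling test for the lower replication genes in KO2 was also run after the result was seen and gave a median of -1.12 with upper-quartile scaling, against -1.17.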

Results

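RNA was sequenced from U251, a human glioma cell line, in which a regulatory element of the long non-coding RNA gene HOTAIR had been deleted. The 2 knockout lines, called KO1 and KO2 here, were each treated with temozolomide (TMZ), an alkylating drug used against glioma, at 1 mM for 72 h, or with the solvent DMSO. Each of the 4 groups had 2 libraries, and the labels do not say whether these came from separate cultures. The libraries held 10332900 to 17396200 counts in genes, and 15152 genes passed the expression filter. No RNA-seq library of unedited cells is analysed here, so the effect of the deletion itself could not be measured. The comparisons below ask how each line responded to TMZ, whether the responses differed, and how the lines differed from each other. Log2 fold changes are given with approximate standard errors (SE) from 2 libraries per group, which can be too small for genes with few counts.

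HOTAIR itself was near the limit of detection. It had 2 and 0 counts in the KO1_DMSO libraries, 5 and 5 in KO1_TMZ, 0 and 4 in KO2_DMSO and 5 and 5 in KO2_TMZ, and it was not tested. The deposited counts therefore give no check of the deletion, which the labels place in a regulatory element and not in the gene. MGMT, the enzyme that removes the methyl group TMZ leaves on guanine, had 0 counts in all 8 libraries, each of which allows up to 0.184 to 0.309 CPM (counts scaled to a common library total) at 3 counts.

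None of the 9 tested genes of the HOXC cluster, which surrounds HOTAIR, passed the test for the mean TMZ response, over all genes or adjusted over the list alone (camera adjusted p = 0.833 for the list). HOXC11 and HOXC12, with 2 and 1 counts summed over all libraries, were too low to test, as were HOXC5 and HOXC-AS3. HOXC4 had a log2 fold change of -0.23 ± 0.12 (adjusted p = 0.0883) and HOXC9 of -0.31 ± 0.18 (adjusted p = 0.12). HOXC6 had -0.02 ± 0.13, HOXC8 had 0.39 ± 0.30, HOXC10 had 0.15 ± 0.08 and HOXC13 had -0.10 ± 0.12. The antisense genes HOXC-AS1, HOXC-AS2 and HOXC13-AS had 0.67 ± 0.46, 0.58 ± 0.32 and 0.74 ± 0.44, and without a stated strand setting their reads cannot be told from those of their sense partners. In single lines, 4 of these genes passed over all genes and none adjusted over the list alone. HOXC13-AS rose in KO1 (1.61 ± 0.69), and in KO2 HOXC10 (0.26 ± 0.12) and HOXC-AS2 (1.04 ± 0.48) rose and HOXC9 (-0.70 ± 0.26) fell, calls lost under 4, 5, 8 and 3 alternatives. For the mean response, HOXC10, HOXC-AS2 and HOXC9 gained a call under 2, 2 and 1 alternatives. Of 3 further genes set aside by name, CALCOCO1 fell in KO2 (-1.13 ± 0.08, adjusted p = 1.6e-22) and had -0.12 ± 0.08 in KO1 (adjusted p = 0.17). The difference between these responses passed the test at -1.0 ± 0.11 (adjusted p = 1.4e-12). ZC3H10 fell by 0.92 ± 0.24 in KO2 and had -0.04 ± 0.22 in KO1, with a difference of -0.88 ± 0.32 (adjusted p = 0.021) that was lost under 6 of the alternative settings. ATF1 had 0.14 ± 0.09 for the mean response and a difference of 0.42 ± 0.19 (adjusted p = 0.064).

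TMZ raised interferon-stimulated genes in both lines. All 25 tested members rose, with a median log2 fold change of 3.76, or 3.53 with members at 0 counts set to a floor of 3 counts per group (camera adjusted p = 1.4e-20; adjusted p = 0.185 with an estimated correlation). MX1, an antiviral GTPase, rose from 3.23 ± 1.06 to 184 ± 57.2 CPM in KO1 and from 7.08 ± 0.986 to 507 ± 5.75 CPM in KO2 (SD, n = 2). For the mean of the lines, the log2 fold change was 5.03 ± 0.13 for OAS3 and 2.52 ± 0.06 for IFI44. Of the 10 genes with the largest rises, MX2, RSAD2, OAS2, CMPK2, OAS1, SLC15A3, CXCL8, MX1, OASL and OAS3, at least MX1, the OAS genes and RSAD2 are known interferon targets. MX2 had 2 counts in KO2_DMSO, and its KO2 ratio was 1741-fold (95% counting interval 481.7 to 14380). SLC15A3 had 3 counts in KO1_DMSO, and its KO1 ratio was 85.8-fold (29.0 to 419). The KO1_TMZ libraries differed from each other in this group, with 143 and 224 CPM of MX1 and 10.7 and 23.5 CPM of RSAD2. Only 2 of the 13 macrophage and leukocyte markers were abundant enough to test, CD14 (0.66 ± 0.29, adjusted p = 0.038, lost under 6 alternatives) and CSF1R (-0.02 ± 0.45), and no marker of that list exceeded 3.81 CPM in any library.

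Stress and secretory genes rose as well. Of the 22 genes of the ATF4 and unfolded protein response list, 16 rose and 2 fell (median 0.93, camera adjusted p = 1.4e-13; adjusted p = 0.101 with an estimated correlation), and adjusted over the list alone 16 rose and 3 fell. DDIT3, a stress-induced transcription factor, rose by 2.65 ± 0.07, CHAC1 by 2.77 ± 0.07, STC2 by 3.38 ± 0.09 and the folate enzyme MTHFD2 by 2.05 ± 0.05. Among the 17 secretory and NF-kB inflammatory genes, 11 rose and 4 fell (median 0.89, camera adjusted p = 2.4e-06, and 0.0457 with an estimated correlation). The cytokines IL11 and LIF rose by 4.10 ± 0.07 and 2.25 ± 0.05. The p53 target list went both ways, with 14 of 31 members higher and 11 lower (median 0.03, camera adjusted p = 0.0115; adjusted p = 0.116 with an estimated correlation and 0.356 without the expression filter). It was called in KO1 (adjusted p = 0.0807 with an estimated correlation) and not in KO2. GADD45A rose by 2.35 ± 0.05, AEN by 2.19 ± 0.06 and the cell cycle inhibitor CDKN1A by 1.51 ± 0.04. Of 22 apoptosis regulators, 12 rose and 5 fell (camera adjusted p = 0.0838, and 0.025 without the expression filter), among them PMAIP1 at 1.25 ± 0.06 and BMF at -2.54 ± 0.15.

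Genes of DNA replication and repair by recombination were higher after TMZ. Among 27 G1/S and replication genes, 25 rose and 1 fell (median 0.65, camera adjusted p = 2.6e-10, and 0.0205 with an estimated correlation). DTL rose by 1.94 ± 0.05, the replication licensing factor CDC6 by 1.65 ± 0.05 and MCM7 by 0.76 ± 0.03. Of the 23 Fanconi and homologous recombination genes, 20 rose and 0 fell (median 0.87, camera adjusted p = 2.6e-08; adjusted p = 0.11 with an estimated correlation), with BRCA2 at 2.11 ± 0.09, BRCA1 at 1.68 ± 0.05 and XRCC2 at 1.56 ± 0.06. The G2/M and mitosis list had 18 of 28 members higher and 5 lower and missed the threshold (camera adjusted p = 0.0519), which it passed without the expression filter (adjusted p = 3.0e-04) and with relative log expression scaling (adjusted p = 0.0458). It was called in KO2 (adjusted p = 0.29 with an estimated correlation). TPX2 rose by 0.72 ± 0.04 and KIF20A fell by 1.14 ± 0.05. The alkylation damage repair list had 9 of 19 members higher and 5 lower (camera adjusted p = 0.173), with the nuclease EXO1 at 2.00 ± 0.06 and the glycosylase MPG at -0.72 ± 0.08. Of the 7 tested replication-dependent histone genes, 1 fell, HIST1H4C (-1.41 ± 0.28; camera adjusted p = 0.959 for the list), and histone paralogs may share reads.

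Glial and neuronal markers fell. Of 15 tested astroglial and glioma stem markers, 12 fell and 1 rose (median -0.87, camera adjusted p = 6.3e-15, and 0.0205 with an estimated correlation). GFAP, the astrocyte intermediate filament, fell by 3.78 ± 0.03; FABP7 (-2.54 ± 0.07), the stem cell factor SOX2 (-1.64 ± 0.04) and ID1 (-1.47 ± 0.04) also fell. Among 7 neuronal markers, 5 fell and 2 rose (median -0.76, camera adjusted p = 0.00102; adjusted p = 0.101 with an estimated correlation), with the neurofilament NEFL at -3.28 ± 0.03, TUBB3 at -2.83 ± 0.22 and SYT1 at 1.06 ± 0.07. All 10 tested drug efflux transporters fell (median -0.74, camera adjusted p = 5.8e-05; adjusted p = 0.11 with an estimated correlation), including ABCC3 (-1.49 ± 0.03) and the cholesterol exporter ABCA1 (-1.37 ± 0.06).

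Lysosomal and mitochondrial genes were lower too, and cholesterol genes in KO1. Of 21 cholesterol synthesis genes, 15 fell and 1 rose (median -0.29, camera adjusted p = 0.0062; adjusted p = 0.11 with an estimated correlation), a fall that was called in KO1 and not in KO2, including INSIG1 (-1.41 ± 0.06) and DHCR7 (-1.09 ± 0.05). Of 31 autophagy and lysosome genes, 22 fell and 5 rose (median -0.31, camera adjusted p = 0.0031; adjusted p = 0.187 with an estimated correlation), among them the proteases CTSD (-1.93 ± 0.04) and CTSL (-1.16 ± 0.05). Of 13 mitochondrially encoded genes, 12 fell and 0 rose (median -0.54, camera adjusted p = 8.7e-07; adjusted p = 0.187 with an estimated correlation), with MT-ND1 and MT-ND2 both at -0.77 ± 0.03. Mitochondrial genes took 4.93% and 4.97% of the counts in KO1_TMZ and 3.90% and 3.99% in KO2_TMZ, against 5.21% to 6.58% in the DMSO libraries.

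The remaining lists were not called for the mean response. Of 27 extracellular matrix genes, 10 rose and 15 fell (camera adjusted p = 0.0666; called in KO2 alone, with an adjusted p = 0.29 with an estimated correlation), from CTGF at 1.69 ± 0.03 to TGFBI at -1.74 ± 0.03. Of 22 hypoxia genes, 7 rose and 9 fell (camera adjusted p = 0.355; the median of -0.05 and the mean of 0.23 differed in sign), with PFKFB3 at -1.11 ± 0.04 and PGK1 at -0.62 ± 0.03. Among 41 ribosomal protein genes, 10 rose and 20 fell (camera adjusted p = 0.344) and the list was called in KO1 alone (adjusted p = 0.284 with an estimated correlation), with RPL3 at -0.67 ± 0.03. Of 21 genes neighbouring HOTAIR in 12q13, 3 rose and 11 fell (camera adjusted p = 0.249), including MAP3K12 at -0.83 ± 0.06 and HNRNPA1 at -0.42 ± 0.03. Of 27 HOXA, HOXB and HOXD genes, 4 rose and 11 fell (camera adjusted p = 0.475); HOXB9 rose by 3.46 ± 0.12 and HOXD9 fell by 1.47 ± 0.06. Of 5 epithelial and keratinocyte markers, 2 rose and 2 fell (camera adjusted p = 0.684; median 0.42, mean -0.30), with ESRP1 at 3.52 ± 0.40. Of the 8 endothelial markers, 4 were tested: CDH5 (-4.39 ± 0.18) and KDR (-0.84 ± 0.08) fell, and VWF at -0.90 ± 0.38 and CLDN5 at 1.72 ± 0.66 lost their calls under 6 and 1 alternatives. ALB was the only tested member of the 7 red cell and plasma genes (1.31 ± 0.57, adjusted p = 0.034, lost under 7 alternatives). Except in the ATF4 list, the counts of members that rose and fell were the same adjusted over the list alone.

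In all, 10420 genes changed in the mean of both lines, 5129 upward and 5291 downward, and 2798 of them by a factor of 2 or more (1207 upward, 1591 downward). For each of the 6 counts of genes here, the side with more called genes turned with the scaling or filter, so these balances carry no direction. The 10 genes with the largest falls were AKR1B10 (-6.79 ± 0.22), FOSB (-6.10 ± 0.06), FOS (-5.49 ± 0.05), MIAT (-4.89 ± 0.25), SLC38A3 (-4.72 ± 0.09), AKR1C1 (-4.52 ± 0.09), CDH5, KRT15 (-4.17 ± 0.14), PLXNA4 (-4.16 ± 0.14) and PSD4 (-4.08 ± 0.05). AKR1C1 and AKR1B10 have close paralogs and may share reads with them, which was not tested. Of 23 lists, 12 were called by camera, 6 up and 6 down. In another model, used for splits of the 8 libraries 4 against 4, the TMZ split gave 10 lists. Of the 35 splits, 9 gave at least as many, the TMZ split among them. The rest of these 9 divide the treatments unevenly and so carry part of the TMZ response.

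**Figure D1:**
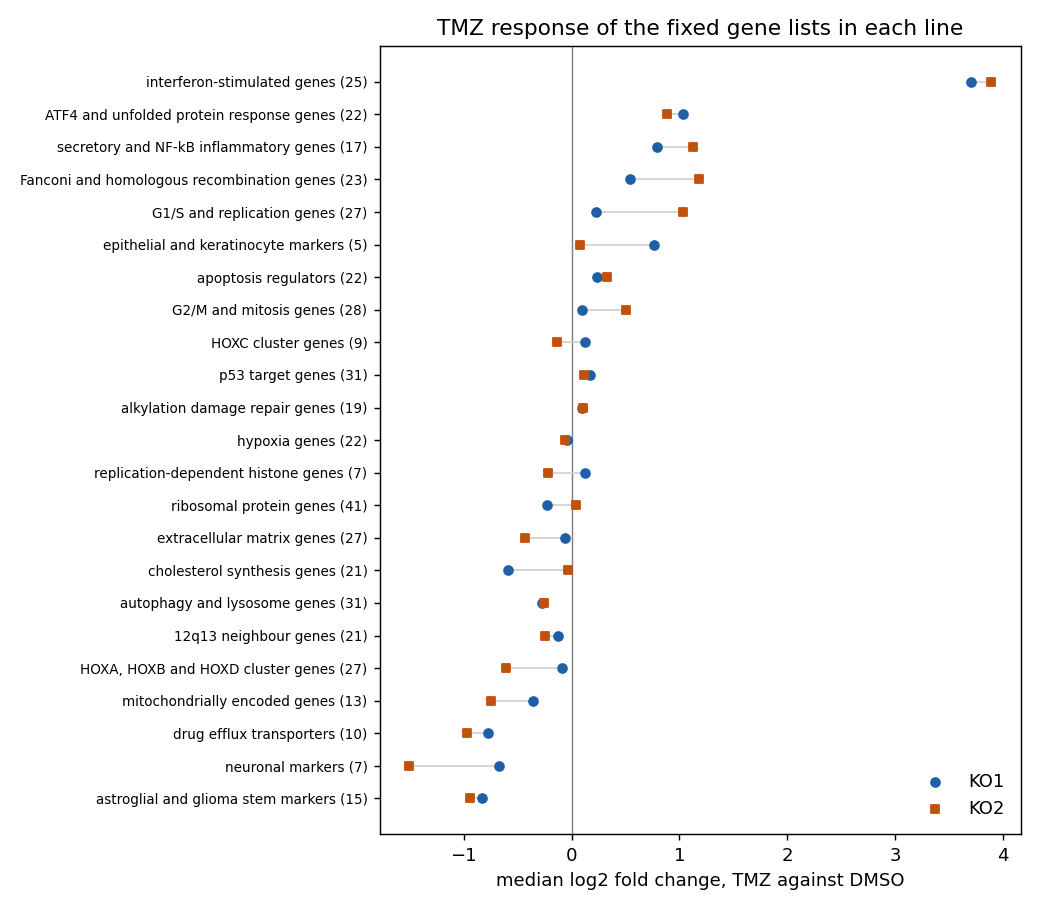
Median log2 fold change by TMZ of each fixed gene list with at least 5 tested genes (number of tested genes in brackets), circles for KO1 and squares for KO2. The interferon-stimulated genes lie at 3.70 in KO1 and 3.89 in KO2, or, with members at 0 counts set to the floor, at 3.63 and 3.37, which turns the order of the lines, and the astroglial markers at -0.83 and -0.94.

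The lines shared the direction of most of their responses, and the response was wider in KO2. In KO1, 8272 genes changed (4046 up, 4226 down), 1934 of them by a factor of 2 or more (943 up, 991 down). In KO2, 9961 changed (4942 up, 5019 down), 3863 of them by a factor of 2 or more (1593 up, 2270 down). Both lines called 2960 genes up and 2997 down, where independent lists would share 1320 and 1400, and 641 genes were called in opposite directions. Across genes, which are not independent replicates, the responses correlated at a Pearson r of 0.629 and a Spearman rho of 0.629. OAS3 rose by 4.65 ± 0.17 in KO1 and 5.40 ± 0.18 in KO2, CDKN1A by 1.94 ± 0.05 and 1.09 ± 0.05, and GFAP fell, at -2.91 ± 0.04 and -4.64 ± 0.05. FOS and FOSB fell in both lines, FOS at -4.27 ± 0.07 and -6.71 ± 0.07 and FOSB at -4.52 ± 0.09 and -7.68 ± 0.08.

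The direction of 5 lists was called in 1 line and not in the other. Cholesterol genes fell in KO1, 19 of 21 with 0 higher (median -0.59, camera adjusted p = 3.0e-08, and 0.0499 with an estimated correlation), while in KO2 6 rose and 8 fell (median -0.04, camera adjusted p = 0.573). Ribosomal protein genes fell in KO1, 31 of 41 with 0 higher (median -0.23, camera adjusted p = 3.7e-04; adjusted p = 0.284 with an estimated correlation), while in KO2 20 rose and 9 fell (camera adjusted p = 0.404). The p53 targets were called higher in KO1, with 13 of 31 up and 7 down (camera adjusted p = 0.00164; adjusted p = 0.0807 with an estimated correlation), against 13 up and 12 down in KO2 (camera adjusted p = 0.102). The difference between these responses was not called (camera adjusted p = 0.816). G2/M genes rose in KO2, 22 of 28 with 4 lower (median 0.51, camera adjusted p = 0.00196; adjusted p = 0.29 with an estimated correlation), against 11 up and 8 down in KO1 (camera adjusted p = 0.993). Extracellular matrix genes were called lower in KO2, with 16 of 27 down and 9 up (median -0.43, camera adjusted p = 0.0104; adjusted p = 0.29 with an estimated correlation), against 11 up and 11 down in KO1 (camera adjusted p = 0.656). Adjusted over the list alone, 32 ribosomal genes fell in KO1 and 14 p53 targets rose in each line, and the other counts were the same. Cholesterol and ribosomal protein genes were already lower in KO2 than in KO1 in DMSO (medians -0.67 and -0.27). In TMZ neither list was called between the lines (medians -0.13 and 0.01, camera adjusted p = 0.0643 and 0.707).

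**Figure D2:**
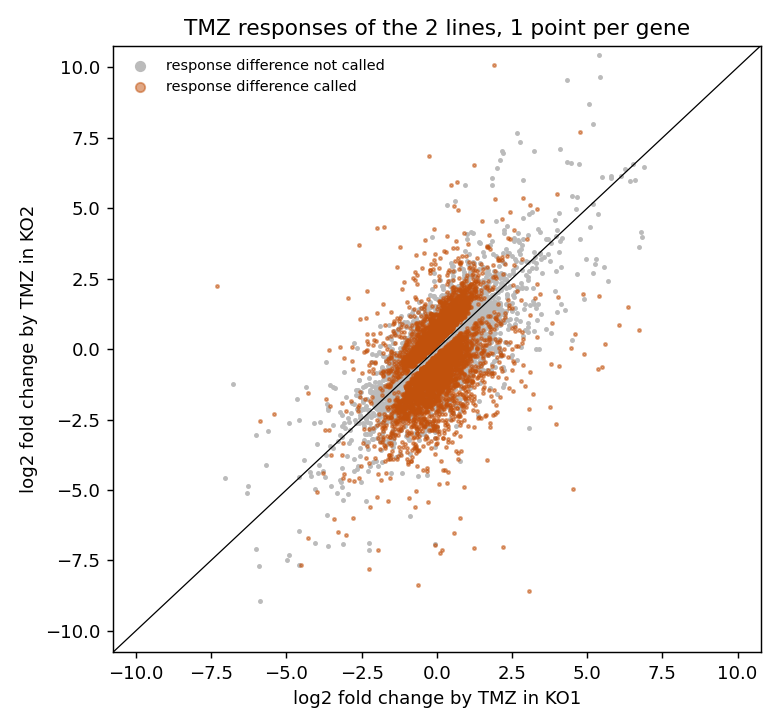
Log2 fold change by TMZ in KO1 (horizontal) and KO2 (vertical) for the 15152 tested genes, with the line of equal response. Orange points are the 6326 genes whose responses differed between the lines, and grey points are the rest.

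The response itself differed between the lines for 6326 genes, 3409 with a higher and 2917 with a lower log2 fold change in KO2. With upper-quartile scaling this balance turned to 2782 higher and 3429 lower, and among the 1639 genes that differed by a factor of 2 or more it was 495 higher and 1144 lower. Replication genes rose more in KO2: 24 of 27 G1/S genes had a higher response and 0 a lower one (median difference 0.88, camera adjusted p = 1.8e-18, and 0.0118 with an estimated correlation). CDC6 differed by 1.51 ± 0.10, FEN1 by 1.36 ± 0.09 and MCM7 by 0.92 ± 0.06. The G1/S genes were lower in KO2 than in KO1 by a median of -1.17 in DMSO and -0.32 in TMZ. Of the 6326 genes, 4565 (72.2%) had the larger line difference in DMSO. There the KO2 libraries stood apart with 2.44% and 2.61% unaligned reads. In the G2/M list 19 of 28 were higher and 0 lower (median 0.38, camera adjusted p = 2.4e-06; adjusted p = 0.267 with an estimated correlation), including AURKA at 1.25 ± 0.10 and TPX2 at 0.83 ± 0.07. Of the Fanconi and homologous recombination genes, 17 of 23 were higher and 0 lower (median 0.62, camera adjusted p = 2.1e-05; adjusted p = 0.267 with an estimated correlation), with BRCA1 at 1.17 ± 0.11. Cholesterol genes, called lower by TMZ in KO1 alone, had a higher response in KO2 for 16 of 21 and a lower one for 1 (median 0.63, camera adjusted p = 1.3e-05; adjusted p = 0.0772 with an estimated correlation), such as INSIG1 at 1.43 ± 0.13. Of 41 ribosomal protein genes, 30 were higher and 0 lower (median 0.33, camera adjusted p = 7.4e-07; adjusted p = 0.267 with an estimated correlation), with RPSA at 0.64 ± 0.06.

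Camera at the preset correlation also called 4 lists with a lower response in KO2. Of these, 2 had called members on both sides and none kept its call with an estimated correlation. Of 27 extracellular matrix genes, 14 were lower and 8 higher (median -0.43, camera adjusted p = 0.00147; adjusted p = 0.286 with an estimated correlation), from COL6A1 at -1.29 ± 0.06 and COL1A2 at -1.26 ± 0.05 to TGFBI at 2.1 ± 0.07. Of 15 astroglial markers, 6 were lower and 4 higher (median -0.21, camera adjusted p = 3.1e-04; adjusted p = 0.107 with an estimated correlation), with the receptor PDGFRA at -2.05 ± 0.09, GFAP at -1.73 ± 0.06 and SOX2 at -1.43 ± 0.07. Of 13 mitochondrially encoded genes, 9 were lower and 0 higher (median -0.37, camera adjusted p = 1.3e-05; adjusted p = 0.286 with an estimated correlation), with MT-CO2 at -0.89 ± 0.05 and MT-CO1 at -0.73 ± 0.05. Among 10 efflux transporters, 6 were lower and 0 higher (median -0.39, camera adjusted p = 0.0117; adjusted p = 0.286 with an estimated correlation), with ABCA2 at -1.38 ± 0.11. Adjusted over the list alone, the called members rose to 25 for G1/S, 22 for G2/M and 31 for ribosomal genes, to 18 and 1 for cholesterol genes, to 4 higher and 7 lower for astroglial markers and to 1 higher and 6 lower for transporters, and the other called lists kept their counts.

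Single genes differed by more. TXNIP, a glucose-responsive inhibitor of thioredoxin, had the largest negative difference (-5.41 ± 0.15), followed by ZNF467 (-5.12 ± 0.71), ARNT2 (-4.42 ± 0.67), TLE2 (-4.38 ± 0.34), HR (-4.25 ± 0.17), ACHE (-4.22 ± 0.29), A2M (-3.83 ± 0.17), CP (-3.81 ± 0.39), DLX6-AS1 (-3.78 ± 0.19) and TMOD1 (-3.58 ± 0.27). CXCL8, a neutrophil chemokine, had the largest positive one at 8.16 ± 0.56, from 1 count in KO2_DMSO, too few for this SE to hold. Its KO2 ratio was 1456-fold (95% counting interval 261 to 57550). DHRS3 (3.56 ± 0.21), KRT81 (3.45 ± 0.18), the amino acid transporter SLC7A5 (3.44 ± 0.08), LIF (3.21 ± 0.11), IFITM10 (3.11 ± 0.52), CMPK2 (2.94 ± 0.72), the G1 cyclin CCND1 (2.92 ± 0.10), the fatty acid desaturase SCD (2.74 ± 0.07) and SPHK1 (2.69 ± 0.19) followed. Interferon-stimulated genes as a list did not differ in response (camera adjusted p = 0.816), though USP18 (0.99 ± 0.21) and IFI27 (-2.18 ± 0.30) did. In the ATF4 list, STC2 differed by 2.45 ± 0.21, TRIB3 by 1.57 ± 0.11 and ATF3 by -2.18 ± 0.15 (camera adjusted p = 0.121 for the list). Of p53 targets, GDF15 differed by 1.91 ± 0.09 and CDKN1A by -0.84 ± 0.07 (camera adjusted p = 0.816). ARNT2 had 2 counts in KO1_DMSO, where its TMZ ratio was 28.2-fold (95% counting interval 7.43 to 239), so its SE is also too small.

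**Figure D3:**
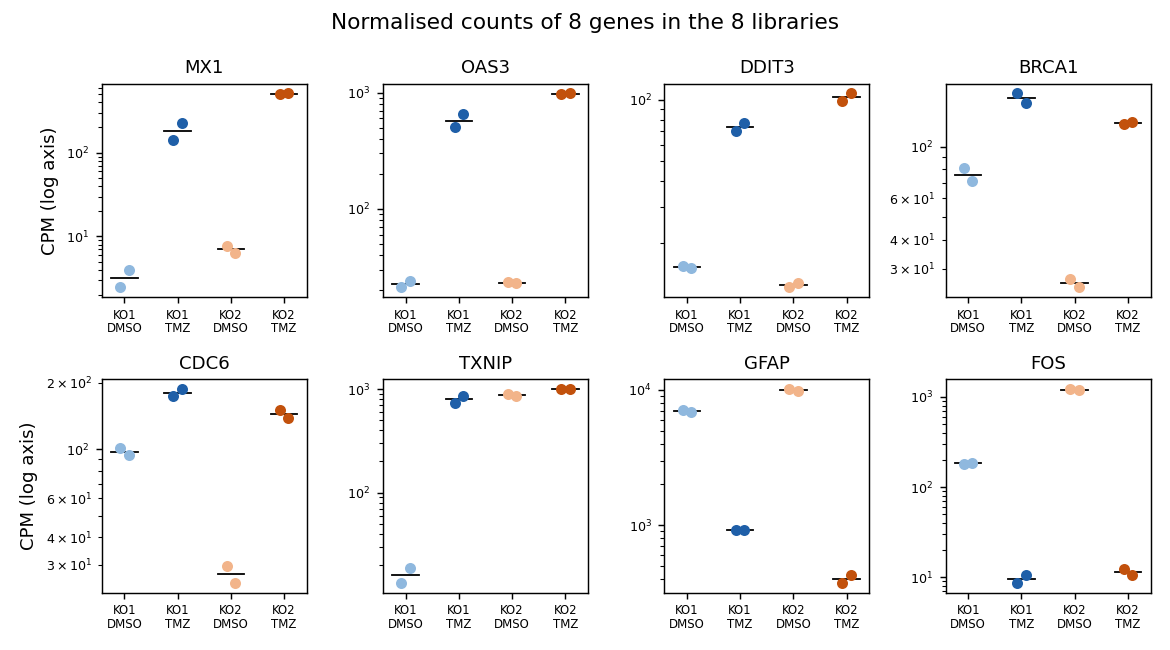
Normalised CPM (log axis) of 8 genes in the 8 libraries, 1 point per library and a bar at the mean of each group's 2 libraries. TXNIP stands at 16.0 CPM in KO1_DMSO against 794 to 997 CPM in the other groups, and CDC6 and BRCA1 are lowest in KO2_DMSO.

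In the DMSO libraries, KO2 had lower proliferation genes than KO1, and higher hypoxia genes by camera at the preset correlation (adjusted p = 0.0694 with an estimated correlation). All 27 tested G1/S genes were lower in KO2 (median -1.17, camera adjusted p = 3.0e-32, and 0.0039 with an estimated correlation) and all 28 G2/M genes were lower (median -0.96, camera adjusted p = 6.8e-29, and 0.03 with an estimated correlation). The mitotic kinase AURKA was lower by a log2 difference of -2.11 ± 0.07, CDC6 by -1.83 ± 0.08, UHRF1 by -1.70 ± 0.07, TPX2 by -1.60 ± 0.05 and FEN1 by -1.56 ± 0.07. AURKA and TPX2 lie in a run of neighbouring genes on chromosome 20 that was lower in KO2. Of the Fanconi and recombination genes, 18 of 23 were lower and 1 higher (median -0.94, camera adjusted p = 4.7e-08; adjusted p = 0.11 with an estimated correlation), with BRCA1 at -1.53 ± 0.08. Alkylation repair genes were lower for 13 of 19 and higher for 1 (median -0.37, camera adjusted p = 0.0127; adjusted p = 0.243 with an estimated correlation), including EXO1 at -1.66 ± 0.10 and APEX1 at -0.59 ± 0.06. Cholesterol genes were lower for 18 of 21 and higher for 0 (median -0.67, camera adjusted p = 3.3e-09, and 0.03 with an estimated correlation), with INSIG1 at -1.82 ± 0.08. Ribosomal protein genes were lower for 35 of 41 and higher for 1 (median -0.27, camera adjusted p = 1.3e-06; adjusted p = 0.254 with an estimated correlation), with RPSA at -0.76 ± 0.04 and RPLP0 at -0.66 ± 0.04.

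Hypoxia genes were higher in KO2 for 14 of 22 and lower for 3 (median 0.93, camera adjusted p = 5.0e-07; adjusted p = 0.0694 with an estimated correlation). The angiogenic factor VEGFA differed by 1.37 ± 0.05, PGK1 by 1.2 ± 0.04 and BNIP3 by 1.05 ± 0.06, whereas the glucose transporter SLC2A1 was lower at -0.95 ± 0.05. PGK1 lies in a run of X-chromosome genes that was higher in KO2. Of 25 interferon-stimulated genes, 9 were higher and 0 lower (median 0.66, or 0.63 with members at 0 counts set to the floor; camera adjusted p = 0.0113; adjusted p = 0.74 with an estimated correlation), with STAT2 at 0.63 ± 0.07 and IFI27 at 2.44 ± 0.26. Efflux transporters were higher for 5 of 10 and lower for 0 (camera adjusted p = 0.047; adjusted p = 0.415 with an estimated correlation and 0.108 without the expression filter), a call that held in 4 of 8 fits with 1 library left out; ABCC3 differed by 1.04 ± 0.05. Adjusted over the list alone, these 9 called lists kept their counts. The KO2_DMSO libraries, used in this comparison, had 2.44% and 2.61% unaligned reads against 1.42% to 1.63% in the other 6. The KO1_DMSO libraries, its other side, had 3.65% and 3.67% of reads outside genes against 4.60% to 5.01% in the rest.

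The lines differed for 8143 genes in DMSO, 3928 higher and 4215 lower in KO2, and 2038 of these by a factor of 2 or more, 1405 higher and 633 lower. With upper-quartile scaling the balance over all called genes turned to 4328 higher and 3732 lower. The largest differences included MLPH, with 0 counts in KO1_DMSO and at least 43.0-fold more in KO2_DMSO against a floor of 3 counts over the group, and ARNT2, at a ratio of 288.1 (95% counting interval 79.3 to 2387). TXNIP was higher in KO2 by 5.73 ± 0.12, PNMA2 by 5.28 ± 0.13, TLE2 by 4.90 ± 0.20, CCDC194 by 4.64 ± 0.36, HR by 4.49 ± 0.12, ZNF467 by 4.42 ± 0.34, ARRDC4, a relative of TXNIP, by 4.30 ± 0.29 and LOXL3 by 4.19 ± 0.18. CTSZ was lower in KO2 at -6.34 ± 0.16, KRT81 at -5.46 ± 0.13, LRRN1 at -3.75 ± 0.26, SCD at -3.15 ± 0.05, LINC02167 at -3.08 ± 0.27, SLC7A5 at -2.91 ± 0.06, ATRNL1 at -2.87 ± 0.32, TINAGL1 at -2.81 ± 0.12 and DHRS3 at -2.78 ± 0.13. CXCL8 was 79.7-fold lower in KO2 (95% counting interval 14 to 3175). HOXD13 had 3 counts in KO1 in either condition and was 97.2-fold higher in KO2 in DMSO (32.8 to 474.8) and 66.9-fold higher in TMZ (22.6 to 327). HOXD9, HOXD13, MLPH and LOXL3 lie in the higher run on chromosome 2 and CTSZ in the lower run on chromosome 20. These runs had median ratios of 1.32 and 0.688 in DMSO, far smaller shifts than those of HOXD13, MLPH, LOXL3 and CTSZ. Near HOTAIR, CALCOCO1 was higher by 0.89 ± 0.07 and ESPL1 lower at -1.39 ± 0.07, while HOXC13-AS (2.13 ± 0.68) and ATF1 (-0.31 ± 0.14) lost their calls under 2 and 7 alternatives.

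After TMZ the lines differed for 5604 genes, 2862 higher and 2742 lower in KO2, 840 of them by a factor of 2 or more (441 higher, 399 lower). With upper-quartile scaling the balance turned to 2528 higher and 3112 lower. G2/M genes were lower in KO2 for 26 of 28 and higher for 1 (median -0.57, camera adjusted p = 7.6e-24, and 0.0395 with an estimated correlation), and G1/S genes for 21 of 27 and higher for 1 (median -0.32, camera adjusted p = 6.0e-09, and 0.0207 with an estimated correlation). Hypoxia genes were higher for 16 of 22 and lower for 1 (median 0.92, camera adjusted p = 4.8e-21, and 0.0207 with an estimated correlation), and secretory genes for 11 of 17 and lower for 1 (median 0.81, camera adjusted p = 4.6e-09, and 0.0207 with an estimated correlation). Interferon-stimulated genes were higher for 19 of 25 and lower for 0 (median 0.92, camera adjusted p = 1.0e-08; adjusted p = 0.411 with an estimated correlation). Astroglial markers were lower for 10 of 15 and higher for 1 (median -0.45, camera adjusted p = 9.6e-07, and 0.0311 with an estimated correlation), and mitochondrial genes for 12 of 13 (median -0.34, camera adjusted p = 4.6e-09; adjusted p = 0.235 with an estimated correlation). The Fanconi list was lower for 10 of 23 and higher for 2 (camera adjusted p = 0.00837), and the ATF4 list higher for 11 of 22 and lower for 4 (camera adjusted p = 0.013), each with an adjusted p = 0.411 with an estimated correlation. Adjusted over the list alone, 23 interferon, 12 secretory, 12 ATF4 and 17 hypoxia genes were higher and 11 Fanconi genes lower, and the G2/M, G1/S, astroglial and mitochondrial lists kept their counts. PNMA2 stayed higher at 3.19 ± 0.09 and CTSZ lower at -6.87 ± 0.18, while TXNIP differed by 0.33 ± 0.08, a call lost under 3 alternatives.

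Part of the difference between the lines lay in 3 runs of neighbouring genes. On chromosome 2, from MBOAT2 to CAPN10, 735 genes had a median log2 difference of 0.40 in DMSO and 0.48 in TMZ, or ratios of 1.32 and 1.40, and 84.2% and 90.6% of them were higher in KO2. On chromosome 20, from PYGB to RTEL1-TNFRSF6B, 190 genes had medians of -0.54 and -0.52, ratios of 0.688 and 0.698, and 84.7% and 95.3% were lower. On the X chromosome, from SPIN4 to IKBKGP1, the genes had medians of 0.56 and 0.55, ratios of 1.47 and 1.46, and 86.1% and 90.8% were higher. The TMZ response of these genes had medians of 0.01, -0.02 and -0.13. Outside the runs the medians were -0.09 in DMSO and -0.02 in TMZ.

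**Figure D4:**
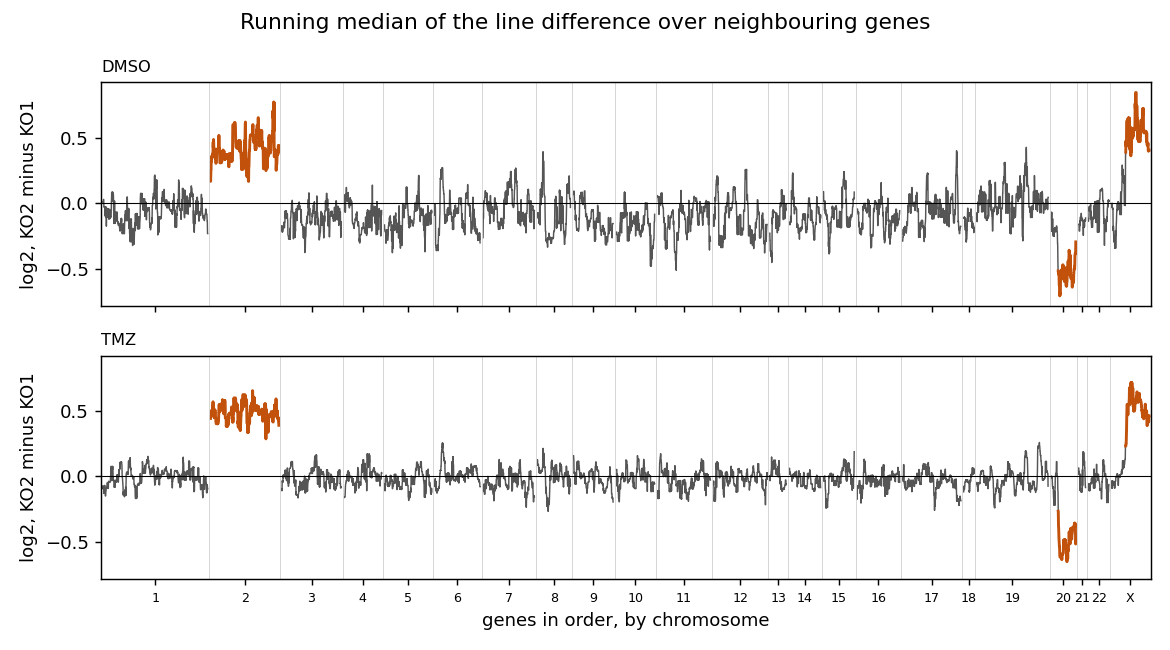
Running median over 31 neighbouring genes of the log2 difference between KO2 and KO1 in DMSO (top) and TMZ (bottom), with genes in chromosome order and the 3 runs in orange. The runs on chromosomes 2 and X lie above 0 and the run on chromosome 20 below 0 in both conditions.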

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

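The leukocyte test, the slope between the line differences, and both counts over splits of the libraries were written down before their values were seen. All other tests in this part were chosen after the result was seen.

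The responses of the lines to TMZ differed, which set these values apart: the response differed between KO2 and KO1 for 6326 genes. The median difference was 0.88 for G1/S and replication genes, 0.38 for G2/M and mitosis genes, 0.62 for Fanconi and homologous recombination genes, 0.63 for cholesterol synthesis genes and 0.33 for ribosomal protein genes. It was -0.39 for drug efflux transporters, -0.43 for extracellular matrix genes, -0.21 for astroglial and glioma stem markers and -0.37 for mitochondrially encoded genes. With an estimated correlation only the G1/S list kept its call (adjusted p = 0.0118), and the other 8 lists had an adjusted p of 0.0772 to 0.286.

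Single genes stood out by the same difference between the lines. Stronger or less negative responses in KO2 were found for CXCL8 (8.16), DHRS3 (3.56), KRT81 (3.45), SLC7A5 (3.44), LIF (3.21), IFITM10 (3.11), CMPK2 (2.94), CCND1 (2.92), SCD (2.74), SPHK1 (2.69), STC2 (2.45), TGFBI (2.1), GDF15 (1.91), TRIB3 (1.57), CDC6 (1.51), INSIG1 (1.43), FEN1 (1.36), AURKA (1.25), BRCA1 (1.17), USP18 (0.99), MCM7 (0.92), TPX2 (0.83) and RPSA (0.64). Lower responses in KO2 were found for TXNIP (-5.41), ZNF467 (-5.12), ARNT2 (-4.42), TLE2 (-4.38), HR (-4.25), ACHE (-4.22), A2M (-3.83), CP (-3.81), DLX6-AS1 (-3.78), TMOD1 (-3.58), FOSB (-3.16), FOS (-2.44), EGR1 (-2.33), IFI27 (-2.18), ATF3 (-2.18), PDGFRA (-2.05), GFAP (-1.73), SOX2 (-1.43), ABCA2 (-1.38), COL6A1 (-1.29), COL1A2 (-1.26), CALCOCO1 (-1.0), MT-CO2 (-0.89), ZC3H10 (-0.88), CDKN1A (-0.84) and MT-CO1 (-0.73).

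Interferon-stimulated genes were higher in the TMZ libraries of both lines. Leukocytes mixed into the libraries would add leukocyte markers, but these gained only 0.0171% of the CPM that the interferon genes gained, which excludes that cause. Under relative log expression, upper-quartile or no scaling of the libraries, the lowest median was 3.74, which excludes the choice among these scalings. With any single TMZ library left out, the lowest median in a line was 3.38, which excludes a single library as the cause.

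Replication and mitosis genes were lower and hypoxia genes higher in KO2 than in KO1 in DMSO, the hypoxia list with an adjusted p = 0.0694 with an estimated correlation. At equal totals the median of the G1/S genes was -1.22. Thinning leaves the expected ratios between libraries unchanged, so this could not test unequal total counts as a cause. A single library under the wrong line label was excluded, since the smallest gap between the libraries of the lines over the 3 runs of neighbouring genes was 0.407, but line names exchanged throughout would leave this gap and were not tested. A culture state of the KO2_DMSO cells at harvest could not be told from a lasting difference that TMZ masks. A culture state of the KO1_DMSO cells, the other side of this comparison, was not tested. Their libraries also stood apart, with 3.65% and 3.67% of reads outside genes against 4.60% to 5.01% in the other libraries. The slope of the TMZ differences on the DMSO differences was 0.176 outside the runs. The G1/S median was -0.32 in TMZ against -1.17 in DMSO, and the G2/M median kept more of its size, at -0.57 against -0.96. For the hypoxia genes, the median in TMZ was 0.92, which argues against a culture state of the KO2_DMSO cells alone. Of the 22 tested, 4 (INSIG2, KDM3A, PDK1 and PGK1) lie in the runs, and the median without them was not taken.

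The lines differed over 3 runs of neighbouring genes on chromosomes 2, 20 and X. A chance order of genes was excluded for the highest window alone, whose median was 0.688 in the real order against at most 0.381 in shuffled order. The shuffles were not scored by the rule for runs, so chance order was not tested for each run. The chromosome medians outside the runs reached at most 0.175, but the runs were chosen for their shift, so this does not test scaling of the libraries. A scaling factor moves all genes of a library alike. The runs had DMSO medians of 0.40, -0.54 and 0.56, on both sides of 0, which argues against scaling as their common cause. A different DNA copy number of these chromosome parts in the 2 lines remains a candidate explanation: runs found in the TMZ libraries alone had a DMSO median of at least 0.404 in size and the same sign. No DNA was measured, so this is a hypothesis.

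Regrouping the 8 libraries 4 against 4 gave 35 splits, with the line in the model for all but the split of KO1 against KO2. For the number of genes, 1 split, the TMZ split itself, reached its 8084 genes. The next highest, 390, is the split of KO1 against KO2, a real difference between the groups. The other splits gave at most 2, but they leave the TMZ response in the residuals and could hardly call genes. This count of splits therefore cannot decide whether chance gave the number of genes. For the number of gene lists, 9 splits, the TMZ split among them, reached its 10 lists, and the highest gave 12. The rest of these 9 divide the treatments unevenly and so carry part of the TMZ response. They do not measure chance, which is therefore not excluded as a source of that number of lists.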

How the results depend on the processing

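The number of genes called depended most on whether a minimum change was asked for. With a change by a factor of 2 or more in addition, 2798 of 10420 genes remained for the mean TMZ response, 1934 of 8272 in KO1, 3863 of 9961 in KO2, 1639 of 6326 for the difference between responses, 2038 of 8143 for the lines in DMSO and 840 of 5604 for the lines in TMZ.

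The number of lists called depended on the test. For the mean response, 12 lists were called at the preset correlation, 3 with an estimated correlation and 21 with fry; for the lines in DMSO these were 9, 3 and 17. Without the expression filter 13 and 8 lists were called, and for the mean response the p53 list was lost and the G2/M list (adjusted p = 3.0e-04) and apoptosis regulators (adjusted p = 0.025) were gained. The G2/M list was also gained with relative log expression scaling (adjusted p = 0.0458). The side with more called genes turned with the scaling or filter for each count of genes.

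With a replicate block, as if replicates were paired by number, 10405, 8310, 9970, 6375, 8180 and 5671 genes were called in the same order, and 14 and 10 lists. The G2/M (adjusted p = 0.0497) and extracellular matrix lists were gained for the mean response. The replicate numbers do not pair libraries, as correlations of paired residuals were at most 0.032.

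With 1 library left out, the counts ranged from 9741 to 10177, 7071 to 8207, 8921 to 10131, 5493 to 6128, 6881 to 8382 and 4198 to 5497. With every library thinned to the lowest gene count total, chosen after the data were seen, 10071 genes were called for the mean response, 5997 for the difference and 7801 for the lines in DMSO. Without the genes of the runs, 5664, 7121 and 4606 remained for the difference and the lines in DMSO and TMZ. The correlation of the responses was 0.568 to 0.614 with 1 library left out and higher with the strict filter.

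Of 3179 alternative values for the named genes, 3112 kept their call or their lack of one, 60 lost a call and 7 gained one. With a call in either fit, 0 changed direction, and changes of direction without a call were not counted. In the main fit 197 of 213 values were called. Many named genes were chosen for a low p or a large change, so these shares are higher than for a typical gene.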

Other observations

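Some observations outside the comparisons asked for stood out, and the gene groups named here were chosen after the values were seen and were not tested as lists. Targets of NRF2, the regulator of the oxidative stress response, and pentose phosphate genes were lower after TMZ: of 21 tested, 19 fell and 0 rose in the mean of the lines (median -1.86), 21 fell in KO1 (median -2.22) and 17 in KO2 (median -1.83). NQO1 fell by 2.04 ± 0.03, and AKR1B10 and AKR1C1, among the largest falls, belong to the same group. The cause was not tested.

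Immediate-early genes, which respond to growth factors and stress within minutes, differed between the lines in DMSO. Of 15 tested, 12 were higher and 2 lower in KO2 in DMSO (median 1.92), against 7 and 2 in TMZ (median 0.15). EGR1 was higher in KO2 in DMSO by 2.77 ± 0.05 and fell with TMZ, at -0.65 ± 0.05 in KO1 and -2.98 ± 0.05 in KO2. Such genes also change with the handling of cells before lysis, which the labels do not describe and which was not tested.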
